A study of Mus musculus with 12 samples.

How the data were processed

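RNA-seq was measured in whole-kidney total RNA from 12 adult mice of a Pkd1 model, with 1 library per mouse as the labels list them. The title of sham CrePlus replicate 1 gives a group name where the other titles give an animal number. The labels' protocols state that tamoxifen-induced mice aged 6 to 8 weeks, with or without Cre, had 1 kidney removed (unilateral nephrectomy, UNx) or a sham operation, and that kidney tissue was taken 4 weeks after surgery. Groups were taken from the sample labels: sham CreMinus, sham CrePlus, UNx CreMinus and UNx CrePlus, with 3 libraries each. The labels give no replicate numbers, so replicates are numbered in accession order and pair no samples. Per the labels' protocols, RNA was extracted with a column kit and treated with DNase, and libraries were made with the SMART-Seq v4 kit, which amplifies full-length cDNA and does not mark the strand. Reads of overlapping or antisense genes could therefore not be separated.

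The deposited tables held whole-number read counts per gene and library. Per the submitters' processing notes, FastQC 0.11.5, cutadapt 1.11, HTSeq and DESeq2 were used with the mouse builds mm10 and GRCm38. The aligner, the annotation and the strand setting are not given in the sources used here. Each of the 6 deposited tables had 24067 genes, and the 35 library columns that recurred between tables were identical. The 5 repeated gene symbols had identical counts and were kept once, which left 24062 genes. The deposited tables also held the authors' log2 fold changes with standard errors, their test statistic (a score per gene), p-values and adjusted p-values. A DESeq2 fit with a prior on the fold change gave values that differed from the deposited log2 fold changes by a median of 7.29e-05 for the UNx table with surgery as the only term. For the second version of that table, the median difference was 0.000124 in a fit with terms for Cre status and surgery. The deposited fold changes are therefore shrunken towards 0. The second version of the sham table leaves out sham CrePlus replicate 1. Genes were matched by gene identifier to a reference table for GRCm38 for positions, and 23710 of the genes had one.

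Library totals, as sums of the deposited counts, were 18914300 to 22480895 in 8 libraries and 41699032 to 42785476 in 4 libraries. The deep libraries were the 3 UNx CrePlus libraries and UNx CreMinus replicate 1. The library numbers in the titles were 1749 to 1754 in UNx libraries. In sham libraries they were 1744 to 1748, and 1755 for sham CrePlus replicate 1. The 4 deep libraries were 1751 to 1754. Surgery and depth thus both followed library number, and differences that go with it could not be separated from them. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 14970 genes, and library sizes were scaled by TMM, with factors from 0.926 to 1.05. One model with 4 group means was fitted to all 12 libraries with the quasi-likelihood test (glmQLFit and glmQLFTest). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Mean expression is given as CPM, the values of the cpm function of edgeR, computed from the counts with TMM-scaled library sizes, as mean ± SD over 3 libraries. Fold changes are log2 values with a standard error (SE), computed as the size of the fold change divided by the square root of the quasi-likelihood F statistic. The labels list each sample separately, and p-values measure the spread between these samples. PCR duplicates could not be counted as separate molecules from these tables.

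The comparisons, the tests, the rule for naming genes and 30 gene lists were chosen before the data were examined. The comparisons were CrePlus against CreMinus within sham and within UNx kidneys, UNx against sham within CrePlus and within CreMinus kidneys and averaged over Cre status, and the interaction of Cre status and surgery. CrePlus against CreMinus averaged over surgery was added after the data were examined. Pkd1 and Irf5 were named in every comparison. In each comparison the rule named the 5 called genes with the largest change in each direction, with a mean of at least 1 CPM, with no overlap between the libraries of the groups and without systematic symbols; the interaction had no rule on overlap. It also named up to 4 called members of each list. Where fewer than 10 genes were called, the 5 genes of smallest p in each direction that met the other criteria were named as not passing. For a list that passed without a called member, the rule named its 2 members of smallest p. Results for some single genes are not reported here.

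Of 381 list entries, 365 were matched to a gene in the tables. Lists with at least 3 members among the tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at a correlation estimated from the libraries, and with fry, and p-values were adjusted over the lists of a comparison. Camera compares a list with the other genes, and fry tests whether the list itself moves in one direction. The erythroid and mitochondrially encoded lists had fewer than 3 tested members and gave no result.

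Sex is not in the labels and was read from Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Xist was at 492 CPM or more in 7 libraries and at 1.26 CPM or less in 5, in which the Y-linked genes summed to 157 CPM or more. Alternatives chosen before the data were examined were DESeq2 1.42.0, its size factors in the edgeR model, no filter on low counts, a fit of only the groups compared, a minimum absolute log2 fold change of 1, a term for sex, and leaving out each library. Alternatives added after the data were examined were terms for sex and depth together, the females or the males alone, the deep libraries thinned to 18914300 counts, and a sex term without sham CrePlus replicate 1. The depth term rested on UNx CreMinus, the only group with both depths, whose single deep library is its only male. The fit to males alone held 5 libraries and left 1 residual degree of freedom.

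The tests were checked on simulated counts with 50 genes changed at each of 4 fold changes. For CrePlus against CreMinus in sham kidneys, over 14847 genes, edgeR recovered 44% of genes raised 1.5-fold, 82% raised 2-fold, 100% raised 4-fold and 84% lowered to a fold of 0.5, with 9 unchanged genes called. DESeq2 recovered 56%, 90%, 100% and 88% with 42 unchanged genes called. For the UNx kidneys, over 14851 genes, edgeR recovered 48%, 84%, 100% and 74% with 11 unchanged genes called, and DESeq2 recovered 66%, 86%, 100% and 80% with 45. The simulated spread was that estimated with a sex term (biological coefficient of variation 0.150), which is smaller than without one (0.237), so the recovery is described for that smaller spread only. No 2 libraries of a group agreed within sampling noise, since the chi-square per gene between replicates was 17.2 or more.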

Results

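Gene expression was measured by RNA-seq in kidneys of 12 mice from a Pkd1 model of polycystic kidney disease. CrePlus mice carried Cre, whose induction by tamoxifen in such a model is meant to delete Pkd1, the gene for polycystin-1, and CreMinus mice did not. The mice kept both kidneys after a sham operation or lost 1 kidney (UNx), after which the remaining kidney grows to take over the lost function. Each of the 4 groups had 3 libraries. Summed counts were 18914300 to 22480895 in 8 libraries and 41699032 to 42785476 in the 3 UNx CrePlus libraries and UNx CreMinus replicate 1, and 17228 to 18022 genes had a count in a library. Male libraries were sham CreMinus replicate 3, sham CrePlus replicate 3, UNx CreMinus replicate 1 and UNx CrePlus replicates 1 and 2, and the other 7 were female. Sex separated the libraries along the first principal component, which held 44.3% of the variance. Depth and sex were thus both unevenly spread over the UNx groups, and 14970 genes were tested.

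Pkd1 (gene 18763, GRCm38 chromosome 17, 24548689 to 24596514) is the targeted gene, and Irf5 (gene 27056, chromosome 6, 29526130 to 29541869) encodes a transcription factor of macrophages that the series title names. Pkd1 averaged 65.0 ± 10.3 CPM in sham CreMinus, 52.0 ± 10.5 in sham CrePlus, 56.8 ± 12.9 in UNx CreMinus and 43.4 ± 3.28 in UNx CrePlus kidneys (SD, n = 3). Its log2 fold change with Cre was -0.32 ± 0.18 (SE) in sham kidneys (adjusted p = 1.0) and -0.39 ± 0.18 in UNx kidneys (adjusted p = 0.482), and neither passed. The CrePlus libraries lay below all CreMinus libraries in UNx kidneys and overlapped with them in sham kidneys. The labels do not name the deleted part of Pkd1, so reads from the rest of the gene do not measure the deletion. Irf5 averaged 13.5 ± 2.03, 18.9 ± 3.33, 13.2 ± 2.10 and 17.9 ± 8.56 CPM in the same order of groups. Its log2 fold change with Cre was 0.48 ± 0.29 in sham kidneys (adjusted p = 1.0) and 0.43 ± 0.28 in UNx kidneys (adjusted p = 0.631). The CrePlus libraries lay above all CreMinus libraries for Irf5 in sham kidneys and overlapped with them in UNx kidneys. Within UNx CrePlus kidneys Irf5 was at 14.9, 27.6 and 11.3 CPM in replicates 1, 2 and 3, and without replicate 2 its log2 fold change with Cre in UNx kidneys was -0.02. For UNx against sham, Pkd1 and Irf5 had log2 fold changes of -0.26 (adjusted p = 0.829) and -0.08 (adjusted p = 0.995) in CrePlus kidneys and of -0.20 and -0.02 in CreMinus kidneys (adjusted p = 1.0 for both). Averaged over Cre status these were -0.23 (adjusted p = 0.894) and -0.05 (adjusted p = 0.995), and the interaction was -0.07 and -0.05 (adjusted p = 1.0 for both).

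**Figure D1:**
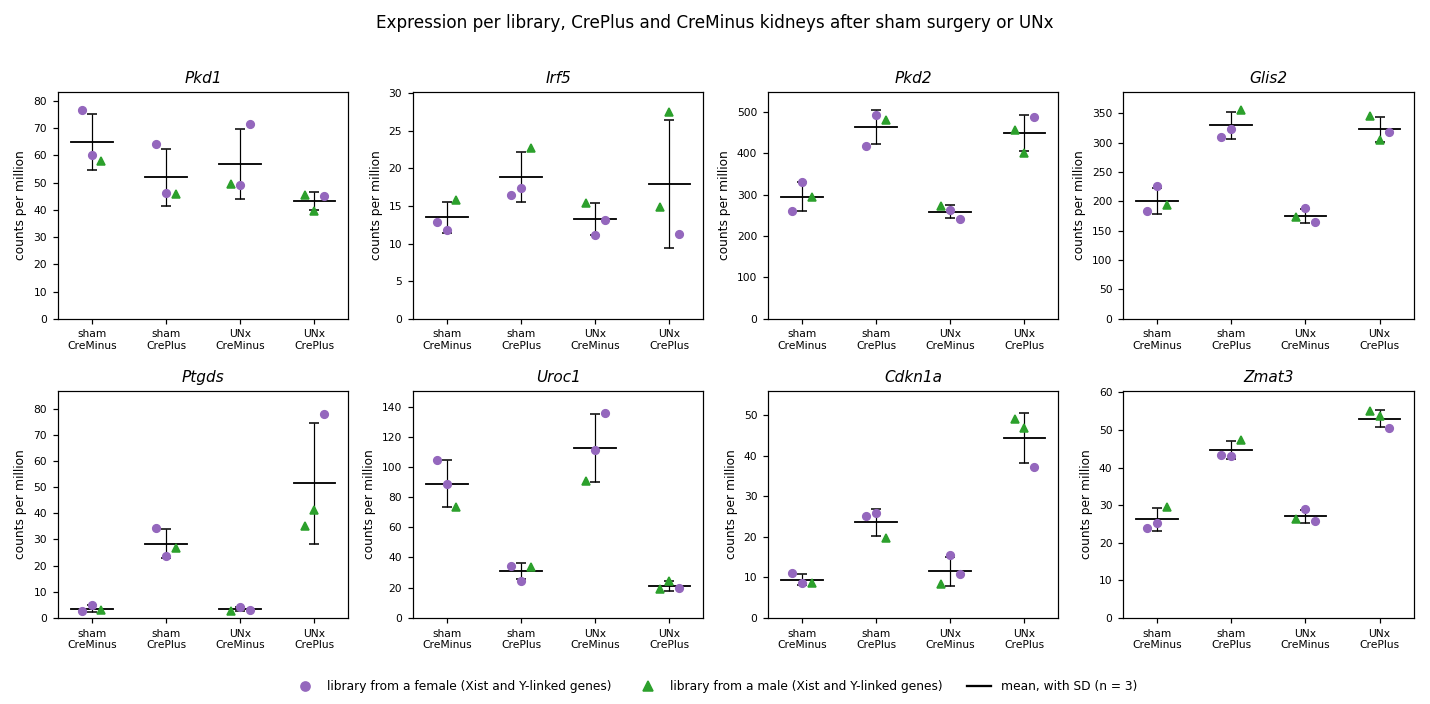
Expression in CPM of 8 genes in each library of the 4 groups, with the mean and SD of 3 libraries, circles for female and triangles for male libraries. Ptgds, Cdkn1a, Zmat3, Glis2 and Pkd2 were higher and Uroc1 was lower in every CrePlus library than in every CreMinus library of the same surgery, while Pkd1 overlapped between CrePlus and CreMinus in sham kidneys and Irf5 in UNx kidneys.

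CrePlus and CreMinus sham kidneys were compared to find what differs with Cre, which is meant to delete Pkd1, in mice that kept both kidneys. Ptgds, Chpf and Zmat3 rose and Uroc1 fell in CrePlus sham kidneys. Ptgds encodes an enzyme of prostaglandin synthesis and Chpf an enzyme of chondroitin synthesis. Zmat3 is a target of the stress regulator p53, and Uroc1 encodes an enzyme of histidine breakdown. With edgeR, 4 genes were called, 3 higher and 1 lower, against 606 at an unadjusted p under 0.05, and DESeq2 called 46. The 606 were a smaller share of the 14970 genes than the 0.05 that chance alone gives. With a sex term 1138 genes had an unadjusted p under 0.05. A fit of only the sham groups called 0. Ptgds (gene 19215, chromosome 2, 25466709 to 25470110) rose by a log2 fold change of 3.02 ± 0.36 (adjusted p = 0.0257), from 3.49 ± 1.39 to 28.3 ± 5.54 CPM. Chpf (gene 74241, chromosome 1, 75474569 to 75479471) rose by 1.10 ± 0.10 (adjusted p = 0.00678), from 20.8 ± 2.25 to 44.5 ± 1.21 CPM. Zmat3 (gene 22401, chromosome 3, 32334792 to 32365665) rose by 0.77 ± 0.09 (adjusted p = 0.0257), from 26.2 ± 2.96 to 44.6 ± 2.42 CPM. Uroc1 (gene 243537, chromosome 6, 90333239 to 90364551) fell by 1.52 ± 0.19 (adjusted p = 0.0301), from 89.0 ± 15.6 to 31.0 ± 5.51 CPM. All 4 had no overlap between the groups, against 8.16% of all genes and 10% by chance. Cables2 (log2 fold change 0.76, adjusted p = 0.0929), Glis2 (0.71, 0.0945), Pkd2 (0.65, 0.235), Cdkn1a (1.32, 0.136), Slc34a2 (0.84, 0.113), Pard6b (0.46, 0.113) and Cdc42bpa (0.46, 0.113) were higher but did not pass. Txnip (-0.98, 0.394) and Lad1 (-1.08, 0.5) were lower but did not pass. In the submitters' deposited test of the 6 sham libraries, 31 genes had an adjusted p under 0.05. Among them were Cdkn1a (adjusted p = 2.24e-08) and Glis2 (adjusted p = 0.000517). Of 12 fits that each left out 1 library, Chpf was called in 11, Ptgds in 4 (adjusted p up to 0.192), Uroc1 in 3 (up to 0.184) and Zmat3 in 2 (up to 0.19). The count was 0 without sham CreMinus replicate 2, where Chpf had an adjusted p of 0.0534. It was 1 without sham CreMinus replicate 1, sham CrePlus replicate 1 or 2, or UNx CrePlus replicate 2, and 2 without sham CrePlus replicate 3, UNx CrePlus replicate 1 or 3, or UNx CreMinus replicate 3.

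Among the gene lists, cystic disease genes, cholesterol synthesis genes, cell cycle genes and tubular injury genes lay higher, and podocyte and endothelial markers lower, in CrePlus sham kidneys with the preset correlation of camera. None of the 8 lists that passed held with an estimated correlation (adjusted p = 0.139 to 0.879), and the lowest adjusted p of fry was 0.0913. The median log2 fold change was 0.62 for cell cycle genes (19 of 20 higher, adjusted p = 2.52e-05), 0.23 for cholesterol synthesis genes (16 of 19, 2.52e-05), 0.31 for tubular injury genes (13 of 18, 0.000233) and 0.17 for polycystin and cystic disease genes (15 of 19, 0.000239). It was 0.10 for glycolysis genes (11 of 12, 0.017) and 0.11 for alternative macrophage markers (7 of 9, 0.0354). Podocyte markers had a median of -0.32 (0 of 8 higher, 0.00421) and endothelial markers of -0.17 (0 of 10 higher, 0.0168). The injury score was 0.76, -0.15 and -0.52 in sham CrePlus replicates 1, 2 and 3, against -0.57 to -0.46 in sham CreMinus kidneys, so the shift rested mostly on replicate 1. The podocyte score was 0.32, -0.01 and -0.59 in the same order, against 0.07 to 0.37, so the fall lay mostly in replicate 3. No list member was called over all genes. Adjusted over the list alone, Glis2 and Pkd2 among the cystic disease genes and Cdkn1a among the injury genes passed, all higher.

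CrePlus and CreMinus UNx kidneys were compared to find what differs with Cre in a kidney under the demand of compensatory growth. The cell cycle inhibitor Cdkn1a and the p53 target Eda2r rose, and Ptgds was again the gene with the largest rise. Pkd2, whose product polycystin-2 forms a complex with polycystin-1, and Glis2, a gene of cystic kidney disease, rose as well. Uroc1, the epithelial gene Lad1 and Reep6 fell. With edgeR, 21 genes were called, 18 higher and 3 lower, against 1598 at an unadjusted p under 0.05, and DESeq2 called 192. The submitters' deposited test of the UNx libraries called 267. Ptgds rose by a log2 fold change of 4.01 ± 0.37 (adjusted p = 0.0019), from 3.22 ± 0.792 to 51.5 ± 23.2 CPM. Cdkn1a (gene 12575, chromosome 17, 29090979 to 29100722) rose by 1.96 ± 0.22 (adjusted p = 0.00635), from 11.5 ± 3.64 to 44.4 ± 6.27 CPM. Eda2r (gene 245527, chromosome X, 97333837 to 97377234) rose by 2.65 ± 0.31 (adjusted p = 0.00738), from 0.999 ± 0.398 to 6.11 ± 1.39 CPM. Uroc1 fell by 2.42 ± 0.20 (adjusted p = 0.000823), from 112 ± 22.7 to 21.0 ± 3.07 CPM. Glis2 (gene 83396, chromosome 16, 4594320 to 4625141) rose by 0.88 ± 0.11 (adjusted p = 0.00936) and Pkd2 (gene 18764, chromosome 5, 104453982 to 104505819) by 0.79 ± 0.12 (adjusted p = 0.0482). Clca1 (2.42), Pcdh7 (1.55) and the YAP target Ajuba (0.53) rose at an adjusted p of 0.0482. Lad1 fell by 1.74 (adjusted p = 0.0359) and Reep6 by 1.08 (adjusted p = 0.0482). All 21 genes had no overlap between the groups, against 15.8% of all genes and 10% by chance.

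Ptgds, Eda2r and Uroc1 were called in UNx kidneys whichever of the 12 libraries was left out. Cdkn1a was not called without UNx CreMinus replicate 3 (adjusted p = 0.0651), and Glis2 was not called without UNx CrePlus replicate 1 or UNx CreMinus replicate 1 or 3 (adjusted p up to 0.114). Lad1 was called in 4 of 12 such fits (adjusted p up to 0.228), Clca1, Pcdh7 and Reep6 in 3 (up to 0.245, 0.282 and 0.268), Pkd2 only without sham CrePlus replicate 3 (otherwise up to 0.268) and Ajuba only without sham CrePlus replicate 1 (otherwise up to 0.205). The number of genes was 13 without sham CreMinus replicate 1, 2 or 3, 10 without sham CrePlus replicate 2, 7 without UNx CrePlus replicate 1 or UNx CreMinus replicate 1, 9 without UNx CrePlus replicate 2, 11 without UNx CreMinus replicate 2, 6 without UNx CreMinus replicate 3 and 48 without UNx CrePlus replicate 3. A term for sex gave 112 genes, which held all 21, while terms for sex and depth gave 8, a fit of only the UNx groups 9 and the females alone, with 1 UNx CrePlus library, 5.

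Macrophage markers, inflammatory products, cell cycle genes, extracellular matrix genes and tubular injury genes lay higher in CrePlus than in CreMinus UNx kidneys with the preset correlation, and markers of the loop of Henle and distal tubule lay lower. None of the 16 lists that passed held with an estimated correlation (adjusted p = 0.22 to 0.43), and the lowest adjusted p of fry was 0.128. The median log2 fold change was 1.15 for macrophage markers (18 of 20 higher, adjusted p = 2.45e-10), 1.10 for cell cycle genes (19 of 20, 4.67e-11), 0.59 for matrix and fibroblast genes (20 of 21, 4.53e-07), 0.50 for tubular injury genes (15 of 18, 2.91e-08) and 0.45 for interferon-stimulated genes (14 of 14, 2.91e-08). It was 1.25 for T and NK cell markers (1.78e-05), 1.09 for alternative macrophage markers (0.000105), 0.89 for proinflammatory macrophage products (0.00025), 0.68 for macrophage growth factors and chemokines (1.84e-05), 0.54 for YAP targets (0.00257), 0.47 for dendritic cell markers (0.0114), 0.43 for the IRF family (0.00135), 0.37 for complement genes (0.0101) and 0.09 for polycystin and cystic disease genes (0.0121). Loop of Henle and distal tubule markers had a median of -0.41 (0 of 12 higher, 1.62e-06) and podocyte markers of -0.34 (0 of 8 higher, 0.00989). The shifts in cell cycle, matrix, injury and loop of Henle lists were seen in the 2 male UNx CrePlus libraries, and the shift in macrophage markers was largest in them. The macrophage score was 0.90 and 0.97 in UNx CrePlus replicates 1 and 2 and 0.06 in the female replicate 3. All 3 lay above the UNx CreMinus libraries (-0.45 to -0.17). Among the females alone, where replicate 3 is the only UNx CrePlus library, the macrophage median was 0.26. In replicates 1, 2 and 3 the score was 1.24, 1.42 and -0.17 for cell cycle genes (UNx CreMinus -0.82 to 0.45), 1.01, 0.64 and -0.02 for matrix genes (-0.63 to 0.18), 1.29, 0.79 and 0.12 for injury genes (-0.58 to 0.26) and -0.64, -0.87 and 0.25 for loop of Henle and distal tubule markers (0.10 to 0.35). Female replicate 3 thus lay within the range of UNx CreMinus kidneys for all 4. Cd74 (1.00, adjusted p = 0.356), Ctss (1.26, 0.378), Cxcl10 (1.45, 0.23), Ccl5 (1.89, 0.291), Timp1 (3.25, 0.374), C4b (2.49, 0.314), Egf (-0.93, 0.329) and Calb1 (-1.08, 0.375) did not pass singly. Adjusted over the list alone, 3 injury genes, 3 interferon-stimulated genes, 2 proinflammatory products, 2 cystic disease genes, 1 chemokine and 1 YAP target passed, all higher, against 1 injury gene, 2 cystic disease genes and 1 YAP target over all genes.

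**Figure D2:**
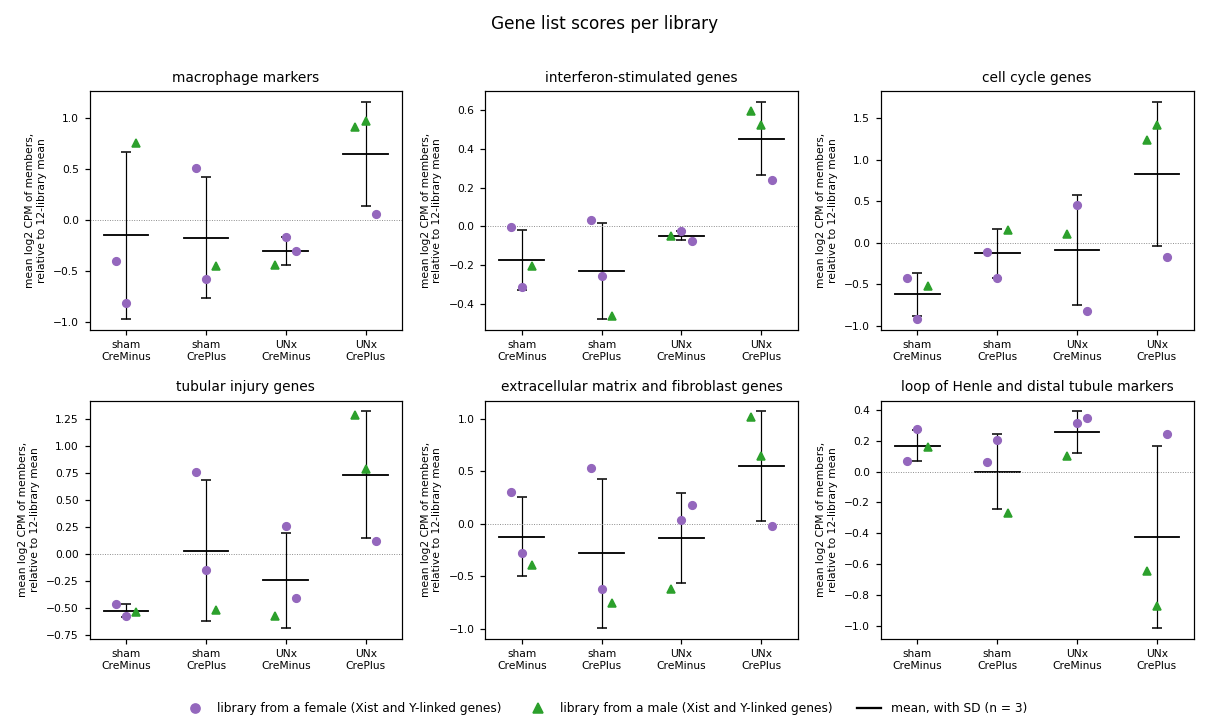
Scores of 6 gene lists in each library of the 4 groups, as the mean log2 CPM of the members relative to the mean of the 12 libraries, with the mean and SD of 3 libraries, circles for female and triangles for male libraries. The macrophage score was 0.90 and 0.97 in the male UNx CrePlus libraries and 0.06 in the female one, against -0.45 to -0.17 in UNx CreMinus libraries.

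The effect of Cre averaged over surgery was added after the data were examined, to find genes that differed with Cre in both kinds of kidney. The estrogen receptor gene Esr1 and the mitotic gene Psrc1 rose beside Ptgds, Eda2r and Cdkn1a. Glis2, Pkd2, Ajuba and the chemokine gene Cxcl16 rose, and Uroc1, Lad1, Scgb1c1, Nsg2 and Pcolce2 fell. With edgeR, 78 genes were called, 58 higher and 20 lower, against 1773 at an unadjusted p under 0.05, and DESeq2 called 391. Ptgds rose by a log2 fold change of 3.52 (adjusted p = 0.000178), Esr1 by 2.60 ± 0.32 (adjusted p = 0.00701), Eda2r by 2.12 (adjusted p = 0.00163), Psrc1 by 1.84 ± 0.25 (adjusted p = 0.012) and Cdkn1a by 1.64 (adjusted p = 0.00108). Glis2 rose by 0.80 (adjusted p = 0.00108), Pkd2 by 0.72 (adjusted p = 0.00607), Cxcl16 by 0.45 (adjusted p = 0.0366) and Ajuba by 0.39 (adjusted p = 0.0213). Uroc1 fell by 1.97 (adjusted p = 0.000167), Lad1 by 1.41 (adjusted p = 0.00825), Scgb1c1 by 2.17 (adjusted p = 0.0366), Nsg2 by 2.03 (adjusted p = 0.0369) and Pcolce2 by 1.68 (adjusted p = 0.039). Esr1 was at 5.12 ± 2.79 and 6.16 ± 3.37 CPM in sham and UNx CreMinus kidneys and at 29.3 ± 2.22 and 40.5 ± 16 CPM in sham and UNx CrePlus kidneys. Cre proteins induced by tamoxifen, as stated for these mice, are joined to a part of the estrogen receptor, and the labels do not name the construct. Esr1 reads from it were not separated from the native gene, so a rise of native Esr1 is not shown.

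All 78 genes had the same direction in sham and in UNx kidneys, which is largely fixed by calling them on the average of both effects. The sizes were larger in UNx kidneys for 61 and in sham kidneys for 17. These genes are not independent, depth and sex were uneven between the UNx groups, and 0 genes were called for the interaction. The median size was 0.55 in sham and 0.83 in UNx kidneys. Across all genes, which are not independent replicates, the Cre log2 fold changes in sham and UNx kidneys had a Pearson correlation of 0.47 and a Spearman correlation of 0.45, and these comparisons share no libraries. Chpf, Ptgds, Uroc1 and Zmat3 were called in both. Ptgds, Esr1, Eda2r, Psrc1, Cdkn1a, Uroc1, Lad1, Glis2 and Pkd2 were called for Cre averaged over surgery whichever of the 12 libraries was left out. Ajuba was called in 5 such fits (adjusted p up to 0.0824), Nsg2 in 4 (up to 0.131), Pcolce2 in 3 (up to 0.138), and Scgb1c1 and Cxcl16 in 2 (up to 0.119 and 0.129). Pkd1, the targeted gene, was called in 0 of these 12 fits (log2 fold change -0.45 to -0.26, adjusted p = 0.215 to 0.554). Irf5 was also called in 0 (0.23 to 0.58, adjusted p = 0.166 to 0.636). The number of genes was 25, 29 and 44 without sham CreMinus replicates 1, 2 and 3, 48 and 40 without sham CrePlus replicates 1 and 2, 28, 36 and 136 without UNx CrePlus replicates 1, 2 and 3, and 46, 31 and 33 without UNx CreMinus replicates 1, 2 and 3.

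With the preset correlation, 16 lists passed for Cre averaged over surgery, and none held with an estimated correlation (adjusted p = 0.363 to 0.649). They were led by cell cycle genes (median 0.86), tubular injury genes (0.55), alternative macrophage markers (0.64), proinflammatory products (0.57), T and NK cell markers (0.53), chemokines (0.45) and macrophage markers (0.44). Dendritic cell markers (0.38), matrix genes (0.28), the IRF family (0.21), interferon-stimulated genes (0.20), YAP targets (0.18), cholesterol synthesis genes (0.16) and cystic disease genes (0.11) were higher as well. Podocyte markers (-0.31) and loop of Henle and distal tubule markers (-0.29) were lower. The 2 male UNx CrePlus libraries stood apart, with cell cycle scores of 1.24 and 1.42 against -0.42 to 0.16 in the other 4 CrePlus libraries and -0.91 to 0.45 in CreMinus libraries. Their alternative macrophage scores were 0.92 and 0.98 against -0.51 to 0.57 and -0.65 to 0.08. By fry the polycystin and cystic disease genes were called (adjusted p = 0.0347). Over all genes 2 cystic disease genes, 1 injury gene, 1 chemokine and 1 YAP target were called. Adjusted over the list alone, 7 injury genes, 2 cystic disease genes, 2 proinflammatory products, 2 alternative macrophage markers, 1 chemokine, 1 T and NK cell marker and 1 YAP target passed, all higher.

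**Figure D3:**
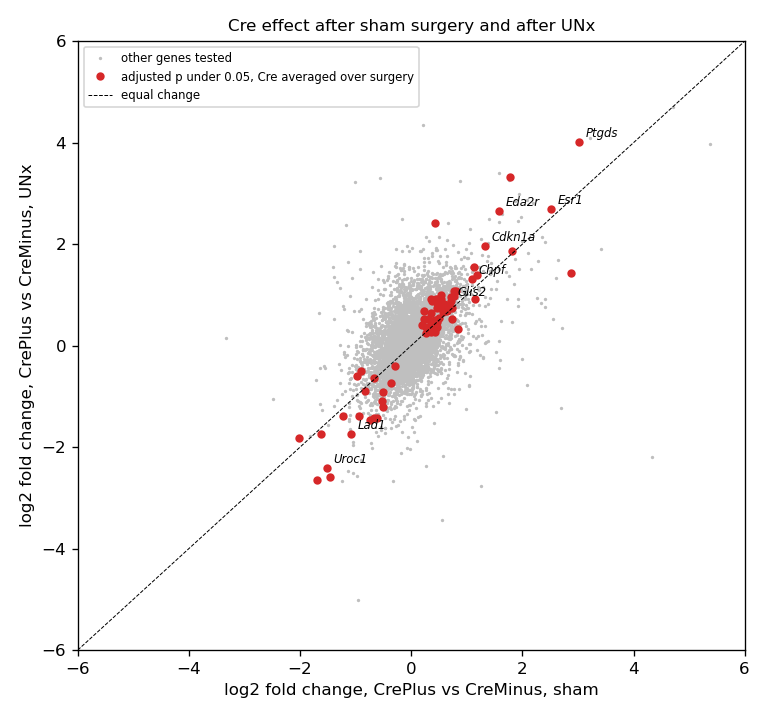
Log2 fold change with Cre in sham kidneys (x axis) against that in UNx kidneys (y axis) for each gene tested, with the 78 genes called for Cre averaged over surgery in red and 4 genes outside the axes. All 78 genes had the same direction in both, which is largely fixed by calling them on the average of both effects.

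UNx and sham CrePlus kidneys were compared to find what compensatory growth changes in CrePlus kidneys. Interferon-stimulated, cell cycle and matrix genes lay higher with the preset correlation. All 3 UNx CrePlus libraries were deep and all 3 sham CrePlus libraries were not, so UNx could not be separated from differences that go with depth. Males were 2 in UNx CrePlus and 1 in sham CrePlus. The calls for cell cycle and matrix genes were lost with an estimated correlation (adjusted p = 0.275 for both). No single gene passed with edgeR, which called 0 genes, against 1022 at an unadjusted p under 0.05. DESeq2 called 11, and the submitters' deposited test of the CrePlus libraries called 15. The genes of smallest p, none of which passed (adjusted p = 0.692), were higher for Aldh1a7 (log2 fold change 0.88), Clca1 (1.94), Cxcl16 (0.55), Mlph (0.51) and the interferon regulator Irf7 (0.90), and lower for Kcnt1 (-1.65), Cish (-1.45), Slc22a4 (-0.39), Pnpla2 (-0.38) and Slc22a19 (-0.72). All 14 interferon-stimulated genes were higher, with a median of 0.70 (adjusted p = 3.23e-20), and 12 passed adjusted over the list alone, against 0 over all genes. This list held with an estimated correlation (adjusted p = 0.0482) and with fry (adjusted p = 0.0285). With a sex term its adjusted p was 0.179 with an estimated correlation and 0.0587 with fry. Its score was 0.59 and 0.53 in UNx CrePlus replicates 1 and 2 and 0.24 in replicate 3.

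The other 14 lists that passed in CrePlus kidneys did not hold with an estimated correlation (adjusted p = 0.275 to 0.514). Cell cycle genes had a median of 1.14 (20 of 20 higher, adjusted p = 7e-18, 15 adjusted over the list alone), matrix and fibroblast genes of 0.73 (21 of 21, 3.6e-14), macrophage markers of 0.87 (18 of 20, 1.3e-09), endothelial markers of 0.40 (9 of 10, 1.08e-06) and tubular injury genes of 0.51 (17 of 18, 2.43e-06). The cell cycle score was 1.24 and 1.42 in the male UNx CrePlus replicates 1 and 2 and -0.17 in the female replicate 3, against -0.42 to 0.16 in sham CrePlus kidneys. The matrix score was 1.01, 0.64 and -0.02 in the same order, against -0.76 to 0.53, so replicate 3 lay within the sham range for both. T and NK cell markers (0.71), proinflammatory products (0.68), chemokines (0.66), immediate-early genes (0.56), alternative macrophage markers (0.53), complement genes (0.46) and the IRF family (0.24) were higher as well. Collecting duct markers (-0.31, adjusted p = 0.00111) and loop of Henle and distal tubule markers (-0.21, adjusted p = 0.0107) were lower. Adjusted over the list alone, 2 IRF genes, 1 chemokine and 1 injury gene passed as higher. Hmox1 (2.52), Pecam1 (0.59), Tagln (0.98) and Cdkn1a (0.91) had an adjusted p of 0.692 with edgeR. In the submitters' deposited test Cdkn1a was called (log2 fold change 0.77, adjusted p = 0.0027). Hmox1 was at 265 CPM in UNx CrePlus replicate 1 and at 37.5 and 16.2 CPM in replicates 2 and 3.

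UNx and sham CreMinus kidneys were compared to find what compensatory growth changes in kidneys without Cre. Cell cycle genes lay higher after UNx in all 20 members with the preset correlation, and this was lost with an estimated correlation (adjusted p = 0.804). Their score was 0.11, 0.45 and -0.82 in UNx CreMinus replicates 1, 2 and 3 and -0.43, -0.91 and -0.52 in sham CreMinus replicates 1, 2 and 3, so UNx replicate 3 lay below 2 of the 3 sham libraries. The phosphate transporter gene Slc34a2 and the transport protein gene Ttr had the smallest p among higher genes, and neither passed. With edgeR, 0 genes were called, against 194 at an unadjusted p under 0.05, and DESeq2 called 2. The 194 were a smaller share of the 14970 genes than the 0.05 that chance alone gives, also with a sex term (385). The 0 calls thus do not show that no gene changed. Slc34a2 (log2 fold change 0.81), Ttr (2.21) and the serine synthesis gene Psat1 (0.91) were higher, and Ajuba (-0.35), Phip (-0.33), Kcnt1 (-1.22), the clock gene Per3 (-0.81) and Dio3os (-0.83) were lower, all at an adjusted p of 1.0. Cell cycle genes had a median of 0.76 (adjusted p = 2.66e-11), tubular injury genes of 0.25 (adjusted p = 0.0442), cholesterol synthesis genes of 0.14 (0.0057), glycolysis genes of 0.13 (0.00564) and interferon-stimulated genes of 0.13 (0.0488). Macrophage markers (-0.29, adjusted p = 0.0442), T and NK cell markers (-0.69, 0.0488) and YAP targets (-0.10, 0.0212) were lower. These 8 lists did not hold with an estimated correlation (adjusted p = 0.804 to 0.931), and fry gave an adjusted p of 0.981. The macrophage median was 0.27 without sham CreMinus replicate 3. Adjusted over the list alone, 1 YAP target, Ajuba, passed as lower, against 0 over all genes.

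UNx and sham kidneys were compared over both Cre states to find the response to the loss of a kidney averaged over both. Cell cycle and interferon-stimulated genes lay higher after UNx, and collecting duct markers lay lower, with the preset correlation. None of the 12 lists that passed held with an estimated correlation (adjusted p = 0.12 to 0.684), and the lowest adjusted p of fry was 0.0878. Slc34a2 and the vitamin D catabolic gene Cyp24a1 were higher and the potassium channel gene Kcnt1 and Per3 were lower, without passing. With edgeR, 0 genes were called, against 848 at an unadjusted p under 0.05, and DESeq2 called 10. The submitters' deposited test of UNx against sham called 5 genes, and its second version called 14. Kcnt1 had a log2 fold change of -1.44 (adjusted p = 0.749), Slc34a2 of 0.55 (0.749), Aldh1a7 of 0.60 (0.78), Per3 of -0.82 (0.78) and Cyp24a1 of 1.88 (0.875). Mlph (0.37), Psat1 (0.85), Sfpq (-0.32), Pnpla1 (-0.41) and Phip (-0.25) also had an adjusted p of 0.875. Without UNx CreMinus replicate 3, edgeR called 14 genes, all lower. Cell cycle genes had a median of 1.03 (20 of 20 higher, adjusted p = 8.8e-23) with 16 passing adjusted over the list alone. Interferon-stimulated genes had a median of 0.42 (14 of 14, 2.39e-15) with 6 passing adjusted over the list alone. The median was 0.38 for matrix genes (2.07e-07), 0.37 for injury genes (2.48e-06), 0.24 for endothelial markers (2.66e-05), 0.37 for immediate-early genes (0.0133), 0.36 for proinflammatory products (0.0212), 0.32 for chemokines (0.0032), 0.29 for alternative macrophage markers (0.00692), 0.23 for macrophage markers (0.00291), 0.13 for the IRF family (0.0452) and -0.26 for collecting duct markers (0.00173). Of the 12 lists, only cell cycle, interferon-stimulated and injury genes passed in the same direction within CrePlus and within CreMinus kidneys. The median in CreMinus and in CrePlus kidneys was -0.29 and 0.87 for macrophage markers, 0.05 and 0.73 for matrix genes, 0.04 and 0.66 for chemokines and 0.01 and 0.24 for the IRF family, so these averages came mostly from CrePlus kidneys. The macrophage value in CreMinus kidneys reversed to 0.27 without sham CreMinus replicate 3 and to 0.33 in females. The cell cycle score was 1.24 and 1.42 in the male UNx CrePlus replicates 1 and 2 and 0.45 in UNx CreMinus replicate 2, while the other 3 UNx libraries (-0.82, -0.17 and 0.11) lay within the range of the 6 sham libraries (-0.91 to 0.16). Adjusted over the list alone, 1 injury gene, 1 chemokine and 1 IRF gene passed as higher.

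The interaction was tested to find genes whose response to UNx differs with Cre status, that is, whether loss of a kidney acts differently in CrePlus kidneys. Macrophage, matrix and interferon-stimulated genes lay higher after UNx in CrePlus than in CreMinus kidneys with the preset correlation, and tubule markers lay lower. None of the 18 lists that passed held with an estimated correlation (adjusted p = 0.198 to 0.55). Among the females alone, macrophage markers (-0.43), tubular injury genes (-0.30) and cell cycle genes (-0.56) lay in the opposite direction, but these values rest on 1 UNx CrePlus library. No single gene passed, so genes called in 1 surgery group only are not shown to differ between them. With edgeR, 0 genes were called, against 277 at an unadjusted p under 0.05, and DESeq2 called 0. The 277 were a smaller share of the 14970 genes than the 0.05 that chance alone gives, also with a sex term (568). The 0 calls thus do not show that no gene differed. Clca1 (log2 difference 2.00), Slfn2 (1.02), Cep97 (0.78), Nlrc5 (1.16) and Ccl19 (1.42) were higher and Tuba8 (-1.94), Dusp23 (-1.34), Apoa2 (-1.62), Uroc1 (-0.90) and Ihh (-0.69) lower, all at an adjusted p of 1.0. With the preset correlation 18 lists passed, 13 higher and 5 lower, led by macrophage markers (1.16) and matrix and fibroblast genes (0.65), both at an adjusted p of 5e-14, and interferon-stimulated genes (0.55, 5.81e-13). Without sham CreMinus replicate 3 the macrophage median for UNx in CreMinus kidneys reversed to 0.27, so the size of 1.16 depends in part on that library. The lowest adjusted p of fry was 0.514, and no list member passed over all genes or adjusted over the list alone.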

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

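The tests of shared variation, of sex and of thinned libraries were chosen only after the result was seen.

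For 18 gene lists, the effect of UNx differed between CrePlus and CreMinus kidneys by a test of the interaction with camera at a preset correlation. With a correlation estimated from the libraries none of the 18 passed (adjusted p = 0.198 to 0.55). At the preset correlation the median log2 difference was 1.16 for macrophage markers, 1.34 for T and NK cell markers, 0.65 for matrix and fibroblast genes, 0.64 for proinflammatory macrophage products, 0.55 for macrophage growth factors and chemokines, 0.55 for interferon-stimulated genes, 0.49 for complement genes, 0.47 for cell cycle genes, 0.41 for YAP targets, 0.30 for tubular injury genes, 0.28 for endothelial markers, 0.22 for the IRF family and 0.17 for alternative macrophage markers. It was -0.27 for loop of Henle and distal tubule markers, -0.26 for collecting duct markers, -0.20 for glycolysis genes, -0.15 for proximal tubule markers and -0.10 for cholesterol synthesis genes. The adjusted p at the preset correlation was 5e-14 to 0.0477. The macrophage value depends in part on sham CreMinus replicate 3, without which the median for UNx in CreMinus kidneys reversed to 0.27.

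Variation that the genes of a list share between libraries may account for these calls, since 0 of the 18 lists kept an adjusted p under 0.05 with a correlation estimated from the libraries, whose median over the lists was 0.382. With a sex term 14 of the 18 lists passed in the same direction at the preset correlation. Other splits of the libraries, fitted without a sex term, gave a median of 8 lists at that correlation. Lists were not counted in splits with a sex term. The 14 calls therefore do not decide on an additive difference between the sexes. That explanation stays open, also for the 4 lists that lost their call. Their medians (and quartiles) went from -0.26 (-0.36 to -0.11) to -0.04 (-0.26 to 0.09) for collecting duct markers, from 0.64 (0.54 to 0.74) to 0.48 (0.05 to 0.58) for proinflammatory products, from 0.47 (0.32 to 0.61) to 0.22 (0.11 to 0.30) for cell cycle genes and from 0.17 (0.12 to 0.52) to 0.23 (0.14 to 0.55) for alternative macrophage markers. The change became smaller in 3 of them and not in the last, and why the calls ended was not tested further. A response to UNx that differs between the sexes stays open, since UNx CrePlus holds 1 female library, and the females alone decide nothing. With the deep libraries thinned, 18 of the 18 lists passed in the same direction, so equal numbers of counts did not end the calls at the preset correlation. Another difference between libraries that goes with depth or with library number stays open. This holds although 17 of the 18 lists passed in the same direction with terms for sex and depth. A bound on that value was set beforehand as evidence against depth, but it was wrong for this design, since only UNx CreMinus holds both depths and its single deep library is its only male. A different response of the immune and stromal cells to UNx in CrePlus kidneys is named by the design and could not be separated from these.

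The libraries were split into groups of the same sizes, with the real grouping counted among the 100 splits. For the interaction, 6 of 100 splits gave at least as many lists as the 18 of the real one. The highest other was 22, so chance is not excluded. For the interaction of single genes the real number was 0, so that all 100 splits gave as many whatever the data and nothing was tested. The highest other split, which separated the sexes, gave 505, which points to a structure of the samples by sex.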

How the results depend on the processing

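All alternatives with females or males alone, thinned libraries or a depth term, the sex term without sham CrePlus replicate 1, and every setting for Cre averaged over surgery were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers that pair the libraries. Fits with a depth term rest on the single deep library of UNx CreMinus for that term, so they do not settle the part of depth. Where a change is given, the cause was not tested, except that fewer libraries were fitted where libraries were left out.

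The number of genes in sham kidneys, 4, became 46 with DESeq2, 10 with a sex term with or without sham CrePlus replicate 1, 8 with sex and depth terms, 7 in females, 41 in males and 0 in a fit of only the groups compared, and ranged from 0 to 3 without 1 library. In UNx kidneys 21 became 192 with DESeq2, 13 with DESeq2's size factors, 112 with a sex term, 128 with a sex term without sham CrePlus replicate 1, 8 with sex and depth terms, 5 in females, 411 in males and 9 in a fit of only the groups compared, and ranged from 6 to 48 without 1 library. For Cre averaged over surgery, 78 became 391 with DESeq2, 295 with a sex term, 217 with a sex term without sham CrePlus replicate 1, 27 in females, 150 in males and 23 at an absolute log2 fold change of at least 1, and ranged from 25 to 136 without 1 library. The 0 genes for UNx in CrePlus kidneys became 11 with DESeq2, 558 in males and 19 with a sex term without sham CrePlus replicate 1. Those for UNx in CreMinus kidneys became 2 with DESeq2 and 23 in males, those for UNx averaged over Cre status became 10 with DESeq2, 138 in males and 14 without UNx CreMinus replicate 3 (range 0 to 14), and those for the interaction became 116 in males. The fit to males left 1 residual degree of freedom.

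Over the 6 planned comparisons 77 list tests passed, which became 1 with an estimated correlation, 1 with fry and 44 in females, and ranged from 60 to 92 without 1 library. Irf5 with Cre in UNx kidneys reversed to -0.10 in females and ranged from -0.0199 (without UNx CrePlus replicate 2) to 0.68 without 1 library. Macrophage markers after UNx in CreMinus kidneys reversed to 0.33 in females and ranged from -0.61 to 0.27 (without sham CreMinus replicate 3). In the interaction, macrophage markers (-0.43), tubular injury genes (-0.30) and cell cycle genes (-0.56) reversed in females, of which UNx CrePlus holds 1. Of 35 results for named genes, 35 kept their direction and their side of the threshold with DESeq2, 35 with a sex term, 34 without the filter, 32 with thinned libraries, 30 with DESeq2's size factors, 26 with sex and depth terms and 16 in females, where 18 were weaker and 1 reversed. In fits without 1 library, 286 were the same, 133 weaker and 1 reversed.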

Other observations

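The tests of depth, of thinned libraries, of sex and of linkage to Pkd1 for the p53 targets and all results for Cre averaged over surgery were chosen after the data were examined.

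The kidney was strongly dimorphic by sex, with 3051 genes that differed between male and female libraries in the fit with a sex term, 1570 higher in males and 1481 in females. Of the male-biased genes listed beforehand, the log2 male minus female difference was 11.87 for Slco1a1 (adjusted p = 5.39e-06), 8.21 for Cyp2j13 (1.82e-09), 8.00 for Slc7a13 (1.44e-06) and 6.16 for Cyp7b1 (3.82e-05). Ugt1a2 (-8.54, 3.82e-05), Igf2 (-4.51, 3.47e-05) and Prlr (-4.41, 6.39e-05) were higher in females. UNx CrePlus replicate 1, a male, had Slco1a1 at 36.4 CPM against 287 to 820 in the other males and Cyp7b1 at 15.4 against 165 to 215. The same library had the stress gene Hmox1 at 265 CPM and the injury gene Lcn2 at 24.1 CPM. Havcr1, another injury gene, was at 121 CPM in UNx CreMinus replicate 2, 74.8 in UNx CrePlus replicate 1 and 74.2 in sham CrePlus replicate 1.

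The following genes called for Cre averaged over surgery were chosen after their values were seen. Cdh3 (log2 fold change 0.94, adjusted p = 0.0351), Wnt9a (0.85, 0.0307), Matn2 (0.77, 0.0489), the DNA synthesis gene Rrm1 (0.68, 0.0302) and Frem2 (0.63, 0.0207) rose. Ppp1r1b (-1.05, 0.0443) and Txnip (-0.78, 0.0479) fell.

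The p53 targets Cdkn1a, Zmat3, Eda2r, Plk2 and Ccng1 were called higher for Cre averaged over surgery. Unequal numbers of counts and an additive difference between the sexes are argued against, since 5 of 5 were still called with the deep libraries thinned and 5 of 5 with a sex term. The p53 targets called in the UNx comparison were Cdkn1a, Zmat3, Eda2r and Plk2, of which Zmat3 was also called in sham kidneys. For 4 of 4 all sham CrePlus lay above all sham CreMinus libraries, which had like totals, so read depth does not account for that sham difference. The sham libraries took part in the fit that called these genes, so they are not an independent check. A part of read depth in the UNx difference stays open. For 1 other, Ccng1, all sham CrePlus libraries also lay above all sham CreMinus libraries (log2 fold change 0.57 ± 0.13). Ccng1 was called only on the average, of which this sham difference is a part, so read depth stays open for it. Linkage to Pkd1 is argued against for 4 of the 5 genes, which lie on other chromosomes, and stays open for Cdkn1a, which lies 4.49 Mb from Pkd1. Linkage of 1 of the genes to the Cre site, which the labels do not name, stays open, and the permutation p of 0.235 for the fullest window of 10 Mb does not bear on it. A bound on that value was set beforehand as evidence against linked passenger loci, but it was wrong, since crowding of called genes does not measure linkage to either site. The 19 targets looked at first, which include the 5 genes, had a median of 0.34 (17 higher), and the 14 of them that were not called had a median of 0.14. A general rise by about 0.34 is argued against, since 23 held-out targets had a fry p of 0.107, a median of 0.03 (14 higher) and an upper quartile of 0.18. A smaller rise, or a rise of some targets only, stays open. The held-out Gdf15 (0.89, adjusted p = 0.0852) and Ckap2 (0.91, adjusted p = 0.416) were named after their values were seen. Both lay above the smallest of the 5 called changes (0.62) without passing in the fit without a sex term. With a sex term 1 of the 23 held-out targets was called higher, with a list median of 0.05 and a fry p of 0.195. A DNA damage response to Cre activity and a response to a loss of Pkd1 may both raise these genes, and the design does not separate them.

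Splits of the libraries into groups of the same sizes were fitted to see whether chance can be excluded. The real grouping is counted among the splits in every share. For 78 genes with Cre averaged over surgery, 3 of 100 splits gave as many. Few splits did so, but this comparison was added after the data were examined, so the share does not exclude chance. The highest other split, which put 5 males against 0, gave 823 and points to a structure of the samples by sex. With a sex term 1 of 100 splits, the real one itself, gave the 295 genes, and the highest other gave 11. For UNx averaged over Cre status the real number of genes was 0, so that all 100 splits gave as many whatever the data and nothing was tested. The highest other, with 5 males against 0, gave 2471. For lists, 28 of 100 splits gave as many as the 12 for UNx averaged over Cre status (highest other 21) and 20 of 100 as many as the 16 for Cre averaged over surgery (highest other 22), so chance is not excluded.

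The 10 splits of 3 against 3 libraries, the real one included, are too few for a share under 0.05. The real and the highest other number of genes were 4 and 0 for Cre in sham kidneys, and 21 and 0 for Cre in UNx kidneys, where 1 of 10 splits gave as many. They were 0 and 21 for UNx in CrePlus kidneys, where the higher split put 3 males against 0, and 0 and 0 for UNx in CreMinus kidneys. With a real number of 0, 10 of 10 splits give as many whatever the data. The numbers of lists were 8 and 18 for Cre in sham kidneys (8 of 10 splits), 16 and 19 for Cre in UNx kidneys (3 of 10), 15 and 18 for UNx in CrePlus kidneys (3 of 10) and 8 and 10 for UNx in CreMinus kidneys (4 of 10). The median of the other splits was 7 to 9 lists in every comparison, so lists called at the preset correlation carry little evidence by themselves.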
